A study of Mus musculus with 6 samples.

How the data were processed

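Gene expression was measured by RNA sequencing in 6 samples of cultured neonatal rat heart cells, 3 kept in conditioned medium of wild-type mast cells (WT medium) and 3 in that of mast cells lacking Alox5 (Alox5KO medium), with TNF-alpha given to the mast cells in both. The sample labels set the group and the replicate number. No sample without mast cell medium, and none with medium of unstimulated mast cells, was analysed here.

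RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the mouse build mm10 are listed without roles, per the submitters' processing notes. The organism is given as mouse, per the labels, but the table holds rat genes: 32883 of its 33682 rows carry rat Ensembl identifiers, 0 carry mouse ones, and 799 carry identifiers of unannotated loci. The rat genome build is not given in the sources used here, so coordinates are printed as the table gives them. Gene symbols were taken from the table. The authors deposited FPKM values, fragments scaled to the length of the gene and to the size of the library, with 1 column per sample and the gene length, biotype and position of every row, per the file headers. Whether counting used strand is not given in the sources used here, so genes that overlap, have antisense partners or share sequence with near-identical copies are uncertain.

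Each FPKM value times the gene's length was a whole multiple of a single step per column, for 100% of values above 0 within 0.05 reads. The reads behind each value were recovered from this step. They summed to between 13284088 and 15766187 per library, and the authors' divisor was 0.990 to 1.03 times that sum. A gene of 1 kilobase with 3 reads would have had between 0.185 and 0.228 FPKM, a limit that covers counting error only. Values at 0 were not read as absence, since Rpl8, which cells need, was listed at 0 in 4 libraries.

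Values were analysed as log2(FPKM + 1), and a log2 fold change on this scale understates the change of genes of low abundance. The 12341 genes with a mean of at least 1 FPKM over all 6 samples were tested, of which 11157 are protein-coding. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and a robust prior, two-sided, with Benjamini-Hochberg adjustment at 0.05, and without a block for the replicate number. Every fold change is Alox5KO medium minus WT medium. The design planned this test for FPKM, and the median log2 fold change of all tested genes was -0.00082.

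A total of 31 gene lists were fixed before the data were examined, covering matrix, contractile, signalling, stress, cell cycle and metabolic genes and cell type markers. Symbols were matched without regard to case, with the most abundant row taken where a symbol recurs. The 29 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 29. Camera called 6 lists higher and 9 lower, and 0 with an estimated correlation. Fry is the rotation test in limma of whether a list's genes move on balance in a single direction. It called 15 lists, not all of them the lists that camera called. Its mixed form, which counts change in either direction, called 26. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone.

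The genes named in the text were chosen by a rule set before the data were examined. They are the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups did not overlap and that have a symbol, up to 4 members with the smallest p from each list described, a fixed set of leukotriene, matrix, TGF-beta and cytokine genes, and the most abundant member of each marker list. A gene named outside this rule is said to be chosen after its values were seen.

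The fit was tested on simulated data for the contrast of Alox5KO medium with WT medium, with reads drawn for the 12341 tested genes at a median dispersion of 0.0111 and 200 genes changed. It recovered 36 of 100 genes changed by 1.5-fold and 87 of 100 changed by 2-fold, with 15 false calls among 12141 unchanged genes. Beside 36 and 87 true calls, these 15 were a larger share of all calls than the threshold for adjusted p allows on average. The simulation changed 200 genes, against 2551 called in the data, so the share of false calls in the data was not estimated. In the same simulation camera called the changed list and 0 of 30 unchanged lists. Genes were drawn independently and the unchanged lists at random, whereas the estimated correlation of the tested lists reached 0.742. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

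Alternatives set before the data were examined were other pseudocounts (0.1 and 0.5), other filters (none, and a mean of at least 5 FPKM), quantile normalization, median-ratio rescaling, TPM (a scaling of each sample to a common sum over the tested genes), a block for the replicate number, limma without trend and robust prior, sample quality weights, precision weights from the recovered reads, a minimum fold change of 1 log2 unit, protein-coding genes alone, and leaving out each sample. Chosen after seeing the data were voom on the recovered reads, removal of a gene length trend with lowess, and thinning of the recovered reads to the smallest library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.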

Results

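RNA sequencing was performed on cultured neonatal rat heart cells that had been kept in conditioned medium, the supernatant taken from another culture. The medium came from bone marrow-derived mast cells stimulated with the inflammatory cytokine TNF-alpha, and those mast cells were either wild type or lacked Alox5. Alox5 encodes 5-lipoxygenase, the enzyme that starts leukotriene synthesis from arachidonic acid. The labels give wild type as the genotype of every sequenced culture, so the 2 groups of 3 samples differed in the donor of the medium. The sample labels call the sequenced cells cardiomyocytes, whereas the design text names a fibroblast culture. Reads recovered from the deposited values numbered 14171423, 13284088 and 14389010 in the WT-medium libraries and 14955850, 15766187 and 15113189 in the Alox5KO-medium libraries.

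All 6 libraries carried high levels of fibroblast transcripts and low levels of cardiomyocyte transcripts. The median fibroblast marker lay between 50.4 and 73.6 FPKM per library, over 24 genes in the table, and Col1a1, the main chain of type I collagen, reached 3290 ± 577 FPKM (SD, n = 3) with WT medium and 3741 ± 483 (SD, n = 3) with Alox5KO medium. The median of 28 cardiomyocyte markers lay between 0.452 and 1.57 FPKM. Markers of mast cells, leukocytes, endothelium, Schwann cells and red cells had medians below those of the smooth muscle and pericyte list in every library. The first principal component of the tested genes held 65% of the variance and separated the groups, and the second, with 11.7%, set WT-medium replicate 3 apart at a score of -25.0. Pearson correlations of log2(FPKM + 1) ran from 0.977 to 0.986 within groups and from 0.928 to 0.943 between groups. No replicate pair was close enough to be a single library deposited again, the closest being WT-medium replicates 1 and 2 with a chi-square of 6.72 per degree of freedom.

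**Figure D1:**
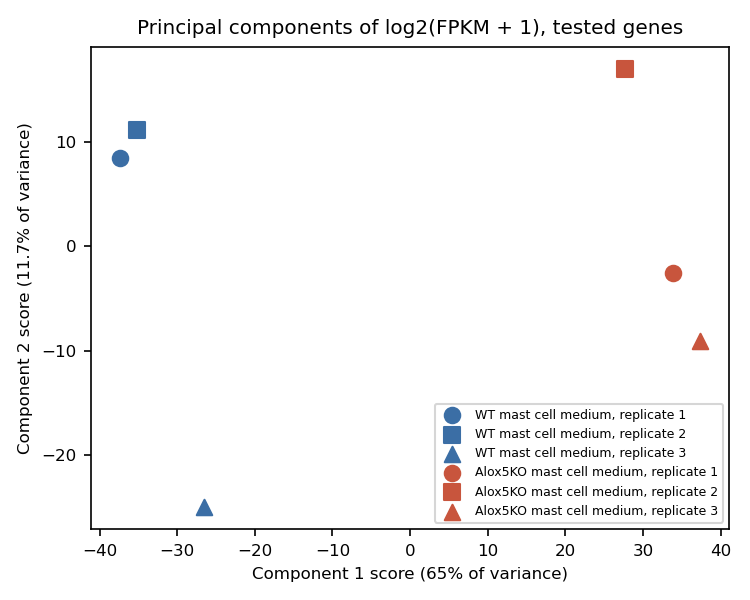
Scores of the 6 samples on the first and second principal components of log2(FPKM + 1) over the tested genes, with colour for the medium and shape for the replicate number. The WT-medium samples lie at -26.5 or below on component 1 and the Alox5KO-medium samples at 27.7 or above.

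**Figure D2:**
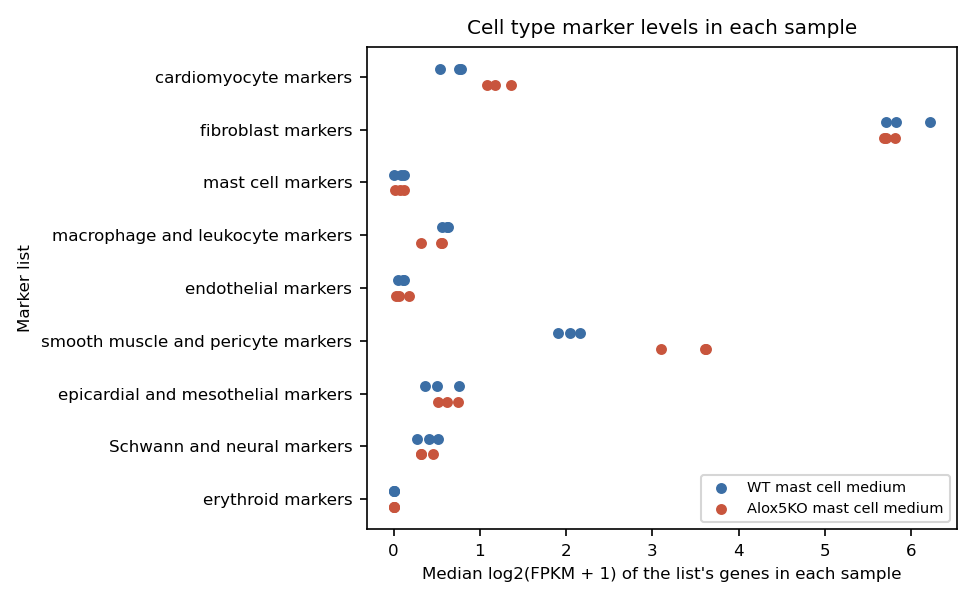
Median log2(FPKM + 1) of each cell type marker list in each of the 6 samples, 1 point per sample, with colour for the medium. Fibroblast markers lie between 5.68 and 6.22 in every sample, and the smooth muscle and pericyte list is the one whose groups lie farthest apart, at 1.90 to 2.16 against 3.10 to 3.62.

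The contrast of Alox5KO medium with WT medium asks which transcripts of the cultured heart cells differ with Alox5 in the activated mast cells. Leukotrienes in the media were not measured here, so their effect cannot be told apart from other differences between the media. Contractile genes rose and inflammatory genes fell in cells given Alox5KO medium. Smooth muscle actin Acta2 went from 340 ± 23.4 to 2775 ± 478 FPKM (SD, n = 3 per group), while the cytokine Il6 went from 186 ± 25.8 to 9.80 ± 4.21 FPKM (SD, n = 3 per group). Of 12341 genes tested, limma with Benjamini-Hochberg adjustment at 0.05 called 1238 higher and 1313 lower, which is 20.7% of those tested. Fold changes of at least 1 log2 unit were seen for 379 of the higher and 409 of the lower genes. Leaving out WT-medium replicate 1 lowered the counts to 791 and 862. The labels do not say that the replicates came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

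Alox5 was itself at a low level in the libraries and fell with Alox5KO medium. Its values were 2.65, 3.28 and 3.47 FPKM with WT medium and 0.436, 0.288 and 0.154 FPKM with Alox5KO medium, from 336 and 35 reads in all. The log2 fold change was -1.68 with a standard error of 0.17 (limma, Benjamini-Hochberg adjusted p = 1.9e-04), and -3.10 with a pseudocount of 0.1. The gene (ENSRNOG00000012972) lies on chromosome 4 from 148398892 to 148446303 in the table's coordinates. Because the knockout was in the mast cells that made the medium, this level checks no label.

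The 10 genes with the largest rises were Pdlim3, Fam180a, Sox9, Gask1b, Igf1, Tgfb3, Cavin2, Lmcd1, Itga8 and Cnn1. Pdlim3, a LIM protein of actin filaments, rose from 4.08 ± 1.44 to 215 ± 44.0 FPKM (SD, n = 3 per group), a log2 fold change of 5.43 with a standard error of 0.22 (limma, Benjamini-Hochberg adjusted p = 5.7e-06). The others rose by between 3.17 for Cnn1, the smooth muscle protein calponin, and 4.54 for Fam180a. Sox9, a transcription factor of cartilage and of fibrotic matrix programs, rose by 4.01, and the growth factors Igf1 and Tgfb3 by 3.58 and 3.48. The 10 largest falls were those of Car4, Il19, Csf3, Serpinb2, Ccl11, Ptges, Pla2g2a, Igfbp5, Wfdc21 and Pvalb. Car4, a carbonic anhydrase anchored to the cell surface, fell from 251 ± 82.3 to 0.115 ± 0.0558 FPKM (SD, n = 3 per group), a log2 fold change of -7.76 with a standard error of 0.25 (limma, Benjamini-Hochberg adjusted p = 3.6e-06). The remaining 9 fell by between 4.60 for Pvalb and 6.76 for Il19 on the log2 scale. Several are secreted products of inflammation: the neutrophil growth factor Csf3 fell by 6.24, the eosinophil chemokine Ccl11 by 5.55 and the secreted phospholipase Pla2g2a by 5.09.

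**Figure D3:**
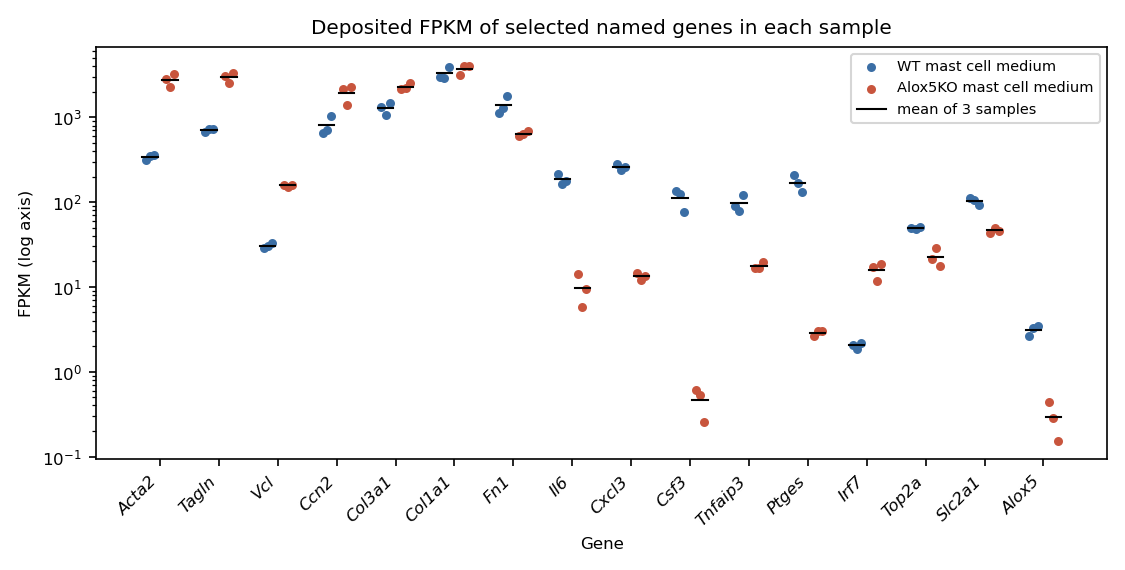
Deposited FPKM on a log axis for 16 selected genes, 1 point per sample with a bar at the mean of 3 samples, WT medium in blue and Alox5KO medium in red. The groups do not overlap for any gene shown except Col1a1, whose means are 3290 and 3741 FPKM.

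Genes of the myofibroblast contractile apparatus rose together. Of 19 tested members of that list, 15 rose and 1 fell, and adjusted over the list alone 16 rose and 1 fell, with a median log2 fold change of 1.29. Camera, the competitive list test in limma, gave a Benjamini-Hochberg adjusted p of 4.2e-11, and adjusted p = 0.23 with an estimated correlation. Vcl, which links actin to adhesion sites, rose from 30.7 ± 1.95 to 157 ± 4.16 FPKM (SD, n = 3 per group), a log2 fold change of 2.32 with a standard error of 0.09 (limma, Benjamini-Hochberg adjusted p = 1.1e-06). Acta2 (chromosome 1, 252537615 to 252550394) rose by 3.01 on the log2 scale, the tropomyosin Tpm1 by 2.12 and the actin-binding protein Tagln by 2.05. Targets of YAP and SRF, transcriptional regulators that respond to actin tension, moved the same way. In that list 14 of 18 tested members rose and 1 fell, 15 and 1 adjusted over the list alone, with a median of 0.86. The Benjamini-Hochberg adjusted p of camera in limma was 3.7e-09, and adjusted p = 0.31 with an estimated correlation. Ankrd1 rose by 2.03, the matricellular Ccn1 by 1.64, the tissue factor gene F3 by 1.33 and Ccn2 by 1.26.

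In the inflammatory lists nearly every gene that passed the test fell. In the NF-kB and TNF response list 22 of 26 tested members fell and 0 rose, the same counts adjusted over the list alone, and the median log2 fold change was -0.98. In the cytokine and chemokine list 19 of 25 fell and 1 rose, 20 and 2 adjusted over the list alone, and the median was -1.71, with 2 rises without WT-medium replicate 3. Camera in limma gave Benjamini-Hochberg adjusted p of 5.2e-15 for the former and 1.7e-13 for the latter, and both had adjusted p = 0.23 with an estimated correlation. Birc3, an inhibitor of apoptosis induced by NF-kB, fell from 39.3 ± 3.51 to 6.76 ± 0.614 FPKM (SD, n = 3 per group), a log2 fold change of -2.38 with a standard error of 0.11 (limma, Benjamini-Hochberg adjusted p = 1.9e-06). Tnfaip3, Ripk2 and Tnip1, regulators of NF-kB signalling, fell by 2.36, 1.78 and 1.64. Il6 (chromosome 4, 3043231 to 3047807) fell by 4.18 on the log2 scale. The neutrophil chemokines Cxcl3 and Cxcl2 fell by 4.18 and 4.10, and Ccl20 fell by 4.09. Cxcl10, the single gene of that list that rose over all genes tested, is induced by interferon and was named after its values were seen. It went from 0.549 ± 0.177 to 11.3 ± 2.64 FPKM (SD, n = 3 per group). Ccl2, a monocyte chemoattractant, stayed abundant, at 3504 ± 269 and 2439 ± 320 FPKM (SD, n = 3 per group), with a log2 fold change of -0.53 (limma, Benjamini-Hochberg adjusted p = 0.022). That call was lost without WT-medium replicate 1, WT-medium replicate 2, Alox5KO-medium replicate 2 or Alox5KO-medium replicate 3, with adjusted p of 0.097, 0.083, 0.077 and 0.072 (limma, Benjamini-Hochberg).

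Ptges and Ptgs2, which act in prostaglandin E2 synthesis, fell as well. Ptges, the inducible prostaglandin E synthase, went from 169 ± 40.1 to 2.89 ± 0.231 FPKM (SD, n = 3 per group), a log2 fold change of -5.43 with a standard error of 0.16 (limma, Benjamini-Hochberg adjusted p = 4.3e-07). Ptgs2, the inducible cyclooxygenase, fell by 2.16, the prostacyclin receptor Ptgir fell by 1.57, and the prostaglandin E receptor Ptger1 rose by 1.195. In the prostanoid list 4 of 11 tested members fell, 1 rose and 6 did not pass, the same counts adjusted over the list alone, with a median of -0.08. Over the alternatives this median ran from -0.65 to -0.03. By camera in limma the Benjamini-Hochberg adjusted p was 0.027, adjusted p = 0.54 with an estimated correlation, and 0.054 without Alox5KO-medium replicate 1.

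Transcripts of leukotriene synthesis were present at unequal levels, and those of leukotriene receptors had few reads or were listed at 0. In that list 20 symbols were matched to the table, with Ltb4r and Ltb4r1 on the same row. Of its members 7 passed the abundance filter, of which 2 fell and 1 rose, the same counts adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.43). Without the filter on low values 15 were tested, 3 fell and 1 rose, and camera called the leukotriene list lower, with a median of -0.15 and an adjusted p of 0.040 (limma, Benjamini-Hochberg). With the filter kept and an estimated correlation, it had adjusted p = 0.68 (camera in limma, Benjamini-Hochberg). Pla2g4a, the phospholipase that releases arachidonic acid, fell by 1.00, while the glutathione transferase Mgst3 rose by 1.12. Lta4h, the leukotriene A4 hydrolase, had 52.1 ± 3.98 and 51.2 ± 3.34 FPKM (SD, n = 3 per group), Mgst2, a glutathione transferase that can make leukotriene C4 and was named after its values were seen, had 27.4 ± 8.42 and 30.8 ± 6.00 FPKM (SD, n = 3 per group), and Dpep1 had a log2 fold change of -0.15 that did not pass the test and ran from -0.30 to -0.01 with 1 sample left out. The cysteinyl leukotriene receptor genes Cysltr1 and Cysltr2 were listed at 0 in all 6 libraries. The leukotriene B4 receptor genes Ltb4r and Ltb4r2 had 26 and 9 reads in the WT-medium libraries together, against 2 and 0 with Alox5KO medium. Ltc4s had 7 and 3 reads, and Alox5ap had 0 and 7, all of the latter in Alox5KO-medium replicate 1. The ribosomal protein gene Rpl8, named after its values were seen, was also listed at 0 in 4 libraries, so a listed 0 does not show that a transcript was absent.

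Interferon-induced genes went up while the inflammatory lists went down. In the interferon list 20 of 31 tested members rose and 3 fell, 23 and 3 adjusted over the list alone, with a median log2 fold change of 0.95. Where the filter was a mean of at least 5 FPKM, 11 of 19 tested members of the interferon list rose and 3 fell, with a median of 0.42. Camera in limma gave a Benjamini-Hochberg adjusted p of 7.8e-09, and adjusted p = 0.45 with an estimated correlation. Irf7, a transcription factor that amplifies interferon production, rose from 2.05 ± 0.183 to 15.9 ± 3.57 FPKM (SD, n = 3 per group), a log2 fold change of 2.45 with a standard error of 0.17 (limma, Benjamini-Hochberg adjusted p = 1.7e-05). The antiviral GTPases Mx2 and Mx1 rose by 2.95 and 1.99, from 0.147 and 0.0652 FPKM, and by 5.13 and 4.32 with a pseudocount of 0.1. Gbp7, a guanylate-binding protein, fell by 1.87, against the direction of most of its list, and the falls numbered 1 without WT-medium replicate 1.

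Genes induced within minutes of a stimulus divided. In the immediate early list 8 of 23 tested members rose and 7 fell, 10 and 8 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.43). Without the filter on low values 11 of 28 rose and 6 fell, and camera called the immediate early list higher, with a median of 0.23 and an adjusted p of 0.022 (limma, Benjamini-Hochberg). With an estimated correlation and the filter kept, it had adjusted p = 0.82 (camera in limma, Benjamini-Hochberg). Nr4a1 rose by 2.53 and Egr1 by 2.04, whereas Klf4 fell by 1.62. Among 16 ERK feedback genes 5 rose and 4 fell, also when adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.85), and the rises numbered 3 without WT-medium replicate 1, WT-medium replicate 2 or Alox5KO-medium replicate 3. The median of the ERK list was -0.17 and its mean 0.14. The receptor kinase inhibitor Spry1 rose by 2.39, the phosphatase Dusp4 by 2.02 and Phlda1 by 1.13, and the transcription factor Etv1 fell by 1.18, or by 1.86 with a pseudocount of 0.1.

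Extracellular matrix genes changed in both directions, and of the fibrillar collagens Col1a1, Col1a2 and Col3a1 the last alone passed the test. Of 38 tested matrix genes 5 rose and 11 fell, 6 and 13 adjusted over the list alone, with a median of 0.00465 and a mean of -0.18 (camera in limma, Benjamini-Hochberg adjusted p = 0.43). Without WT-medium replicate 3 the rises numbered 8. Col3a1, type III collagen, rose from 1285 ± 201 to 2293 ± 186 FPKM (SD, n = 3 per group), a log2 fold change of 0.84 with a standard error of 0.14 (limma, Benjamini-Hochberg adjusted p = 0.0028). Col1a1 and Col1a2 had log2 fold changes of 0.19 and 0.47 and Postn, periostin, one of -0.02, none past the threshold. Col1a2 varied within the WT group, from 336 to 1112 FPKM. With 1 sample left out Col1a1 ran from 0.12 to 0.33, Col1a2 from 0.0048 (without WT-medium replicate 3) to 0.87, and Postn from -0.27 to 0.30. Thbs1, a thrombospondin that activates latent TGF-beta, rose by 1.70, and the collagens Col12a1 and Col14a1 rose by 1.08 and 1.04. Fibronectin, Fn1, fell by 1.10, and the collagen crosslinking enzyme Lox fell by 1.56. The proteoglycan decorin, Dcn, was named after its values were seen. It fell from 2219 ± 711 to 134 ± 66.3 FPKM (SD, n = 3 per group), or by 4.10 on the log2 scale.

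Among the matrix-degrading enzymes the collagenase and gelatinase genes Mmp13 and Mmp9 fell. Among 20 matrix proteases and inhibitors 9 fell and 5 rose, 9 and 6 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.056, and 0.56 with an estimated correlation). Camera called the list lower without WT-medium replicate 1, WT-medium replicate 2 or Alox5KO-medium replicate 3, at adjusted p of 0.033, 0.019 and 0.047 (limma, Benjamini-Hochberg), and at 0.042, 0.039 and 0.022 with a pseudocount of 0.1, without the filter on low values and with TPM scaling. Mmp13 fell by 4.07 to 0.0575 ± 0.0280 FPKM (SD, n = 3), with a log2 fold change of -6.75 at a pseudocount of 0.1, and Mmp9 fell by 2.68. The protease inhibitors moved apart, Timp3 rising by 2.38 and Timp1 falling by 1.88.

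More members of the TGF-beta response list rose than fell. In that list 10 of 29 tested members rose and 5 fell, 11 and 5 adjusted over the list alone. Tgfb3 went from 23.1 ± 4.96 to 267 ± 56.3 FPKM (SD, n = 3 per group), and the pseudoreceptor Bambi, the inhibitor of differentiation Id3 and Ccn2 rose by 1.32, 1.16 and 1.26. The cytokine Il11 fell by 2.04, and Tgfb1 had a log2 fold change of -0.0093 that did not pass the test and ran from -0.14 to 0.09 with 1 sample left out. The Benjamini-Hochberg adjusted p of camera in limma was 0.04996, and adjusted p = 0.56 with an estimated correlation. The call held in 10 of 21 alternatives. It was lost without WT-medium replicate 1, WT-medium replicate 2, Alox5KO-medium replicate 2 or Alox5KO-medium replicate 3, at adjusted p of 0.065, 0.077, 0.074 and 0.088 (limma, Benjamini-Hochberg), and was 0.097 with TPM scaling.

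Mitotic genes fell while replication genes mostly did not pass the test. Of 29 tested G2 and M phase genes 25 fell and 0 rose, and 29 fell adjusted over the list alone, with a median of -0.76. By camera in limma the Benjamini-Hochberg adjusted p was 3.5e-13, and adjusted p = 0.44 with an estimated correlation. The topoisomerase Top2a fell from 49.5 ± 0.750 to 22.4 ± 5.64 FPKM (SD, n = 3 per group), a log2 fold change of -1.13 with a standard error of 0.16 (limma, Benjamini-Hochberg adjusted p = 0.0011). Hmmr, Nusap1 and Birc5, which act on the mitotic spindle, fell by 1.09, 0.94 and 0.94. In the S phase list 2 of 27 fell and 0 rose, also when adjusted over the list alone. The falls numbered 1 in each of the fits without WT-medium replicate 1, WT-medium replicate 2, Alox5KO-medium replicate 1 or Alox5KO-medium replicate 3. They numbered more than 2 without Alox5KO-medium replicate 2. With voom on the recovered reads E2f8 fell as well, at an adjusted p of 0.0498 (limma, Benjamini-Hochberg). The ribonucleotide reductase gene Rrm2 fell by 0.81. For that list camera in limma gave a Benjamini-Hochberg adjusted p of 0.0497, and adjusted p = 0.82 with an estimated correlation. Without WT-medium replicate 1, WT-medium replicate 2, Alox5KO-medium replicate 1 or Alox5KO-medium replicate 3 it was 0.065, 0.25, 0.25 and 0.089, with 0.091 at a mean of at least 5 FPKM and 0.057 with TPM scaling.

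Genes of glucose use, of the hypoxia response and of protein folding in the endoplasmic reticulum fell. In the glycolysis and hypoxia list 20 of 27 tested members fell and 0 rose, 23 and 0 adjusted over the list alone, with a median of -0.62. Camera in limma gave a Benjamini-Hochberg adjusted p of 2.5e-11, and adjusted p = 0.34 with an estimated correlation. The prolyl hydroxylase Egln3 and the hypoxia-induced Ndrg1 had log2 fold changes of -2.16 and -2.15. The glucose transporter Slc2a1 fell from 103 ± 10.1 to 46.4 ± 3.49 FPKM (SD, n = 3 per group), or by 1.13, and the phosphofructokinase Pfkp fell by 0.89. In the unfolded protein and integrated stress list 14 of 27 fell and 2 rose, 16 and 2 adjusted over the list alone, with a median of -0.45 and with 1 rise without WT-medium replicate 1 or 2 or Alox5KO-medium replicate 2 or 3. The Benjamini-Hochberg adjusted p of camera in limma was 3.8e-05, and adjusted p = 0.51 with an estimated correlation. The chaperones Sdf2l1, Hsp90b1, Pdia4 and Calr fell by 1.38, 1.21, 1.00 and 0.85.

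**Figure D4:**
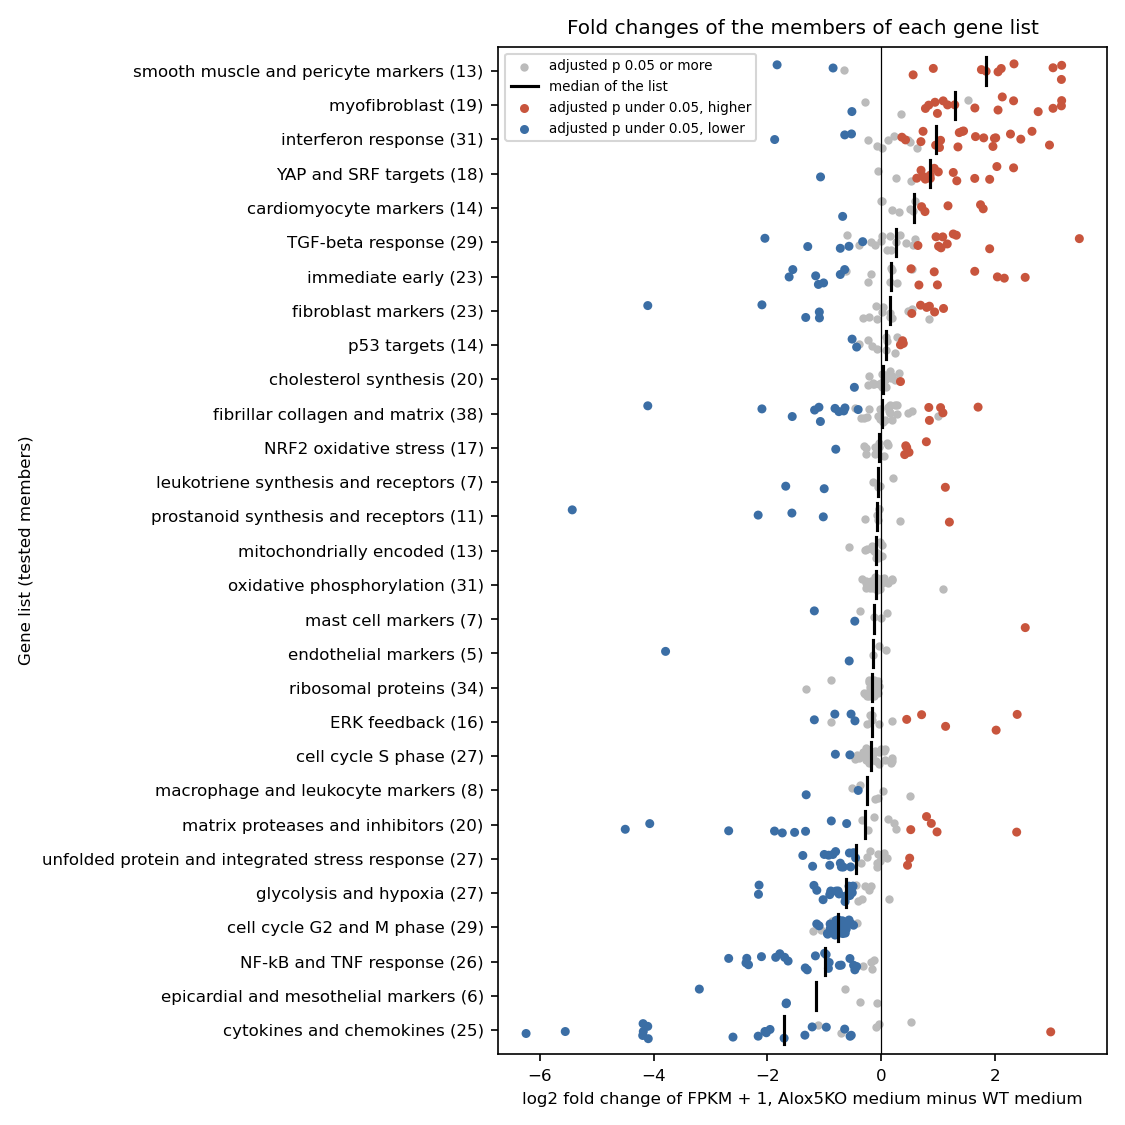
Log2 fold change of FPKM + 1, Alox5KO medium minus WT medium, for every tested member of the 29 gene lists, ordered by the median of the list, which a black line marks. Red points rose and blue points fell at an adjusted p under 0.05, and grey points did not pass. The medians run from -1.71 for cytokines and chemokines to 1.84 for smooth muscle and pericyte markers.

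Several lists held few calls or none. None of 31 oxidative phosphorylation genes, 13 mitochondrially encoded genes or 34 ribosomal protein genes passed the limma test, over all genes or adjusted over the list alone, and unadjusted p under 0.05 was reached by 3998 of all tested genes. Camera in limma gave Benjamini-Hochberg adjusted p of 0.21 and 0.34 for the first pair. It called the ribosomal list lower, at 0.0079 with a median of -0.16, but adjusted p = 0.82 with an estimated correlation and 0.065, 0.098 and 0.074 without WT-medium replicate 1, WT-medium replicate 2 or Alox5KO-medium replicate 2, and the call was also lost with quantile normalization, at 0.27 with a median of -0.06, and with the gene length trend removed, at 0.060. Without WT-medium replicate 3 the falls numbered 4 in the ribosomal, 2 in the oxidative phosphorylation and 1 in the mitochondrially encoded list, and with sample quality weights 3, 4 and 0. Of 20 cholesterol synthesis genes 1 rose and 1 fell, the latter being Mvd, which fell by 0.47, and adjusted over the list alone 0 rose and 1 fell (camera in limma, Benjamini-Hochberg adjusted p = 0.78). The Mvd call was lost without WT-medium replicate 1, at an adjusted p of 0.068 (limma, Benjamini-Hochberg), and the falls numbered 2 without WT-medium replicate 3. The rises numbered 0 without WT-medium replicate 1, WT-medium replicate 3, Alox5KO-medium replicate 1 or Alox5KO-medium replicate 3, and 2 with TPM scaling. Sqle, the gene that rose, also lost its call with the replicate block, at an adjusted p of 0.067 (limma, Benjamini-Hochberg). Of 17 NRF2 targets 5 rose and 1 fell, 5 and 2 adjusted over the list alone, with a median of -0.05 and a mean of 0.05, and camera in limma gave a Benjamini-Hochberg adjusted p of 0.78. Me1 rose by 0.79 and the quinone reductase Nqo1 fell by 0.80. The NRF2 rises numbered 2, 1, 3, 3 and 1 without WT-medium replicates 1, 2 and 3 and Alox5KO-medium replicates 1 and 3. Of 14 p53 targets 3 rose and 2 fell, 4 and 3 adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.78). The p53 rises numbered 0, 0, 1, 1 and 0 without WT-medium replicates 1, 2 and 3 and Alox5KO-medium replicates 1 and 3, and the falls 0 without WT-medium replicate 1 or 2 and 1 without Alox5KO-medium replicate 1, 2 or 3.

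Some markers of other cell types changed as well. Of 13 smooth muscle and pericyte markers, a list that shares 4 members with the contractile genes, 10 rose and 2 fell, the same counts adjusted over the list alone, with a median of 1.84. By camera in limma the Benjamini-Hochberg adjusted p was 2.4e-05, and adjusted p = 0.23 with an estimated correlation. Notch3, a receptor of mural cells, rose by 2.33 and the myosin kinase Mylk by 2.10. Of 14 cardiomyocyte markers 5 rose and 1 fell, 8 and 1 adjusted over the list alone, and 8 rose among protein-coding genes alone. Camera in limma gave a Benjamini-Hochberg adjusted p of 8.6e-04, and adjusted p = 0.45 with an estimated correlation. Tnnt2, cardiac troponin T, went from 22.98 ± 6.92 to 79.9 ± 10.6 FPKM (SD, n = 3 per group), and Actc1, Pln and Tnnc1 rose by 1.74, 1.17 and 0.77, with 1.95 for Pln at a pseudocount of 0.1.

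Fibroblast markers divided, 6 of 23 rising and 5 falling, 7 and 5 adjusted over the list alone, with a median of 0.15 and a mean of -0.14 (camera in limma, Benjamini-Hochberg adjusted p = 0.81). The receptor Pdgfra fell by 1.09, the protease Htra3 by 1.09 and the homeobox factor Meox1 by 1.33, and the cardiac factor Tbx20 rose by 1.09. Of 6 epicardial and mesothelial markers 3 fell and 0 rose, 4 and 0 adjusted over the list alone. The Benjamini-Hochberg adjusted p of camera in limma was 8.6e-04, adjusted p = 0.23 with an estimated correlation, and 0.33 with a median of 0.0062 where genes of low abundance were kept. Aldh1a2, the retinoic acid synthase, fell by 3.20, and Msln and Krt18 fell by 1.67 each, with -3.83 for Krt18 at a pseudocount of 0.1. Of 8 leukocyte markers 2 fell and 0 rose, also adjusted over the list alone (camera in limma, Benjamini-Hochberg adjusted p = 0.11), with 1 fall without WT-medium replicate 1, WT-medium replicate 2, Alox5KO-medium replicate 2 or Alox5KO-medium replicate 3. Coro1a, an actin-binding protein, fell by 1.32. Of 5 endothelial markers 2 fell and 0 rose, also adjusted over the list alone, with 1 fall without WT-medium replicate 2, WT-medium replicate 3, Alox5KO-medium replicate 1 or Alox5KO-medium replicate 3. Ecscr, an endothelial adhesion gene, fell by 3.79. For the endothelial list camera in limma gave a Benjamini-Hochberg adjusted p of 0.077, and 0.033 and 0.047 without WT-medium replicate 1 or Alox5KO-medium replicate 3. The leukocyte list reached 0.022 and the mitochondrially encoded list 0.014 without Alox5KO-medium replicate 1, and the oxidative phosphorylation list 0.016 without WT-medium replicate 3 and 0.043 with sample quality weights. With an estimated correlation these 4 lists had adjusted p of 0.45, 0.64, 0.82 and 0.82 (camera in limma, Benjamini-Hochberg). Of 7 mast cell markers 1 rose and 2 fell, the same counts adjusted over the list alone, with a median of -0.14 and a mean of 0.07 (camera in limma, Benjamini-Hochberg adjusted p = 0.66). Il1rl1, the IL-33 receptor, rose by 2.53 and the carboxypeptidase Cpa3 fell by 1.18. The falls in the mast cell list numbered 1 with TPM scaling and without WT-medium replicate 1, 2 or 3 or Alox5KO-medium replicate 1 or 2. The lists of Schwann cells and red cells had too few tested genes for camera, with Cnp at 39.2 ± 6.07 and 39.4 ± 6.02 FPKM (SD, n = 3 per group) and Ahsp under 0.712 FPKM in every library.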

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

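The alternatives voom on the recovered reads, removal of the gene length trend and thinning to the smallest library were chosen after the data were seen. The counts of 1238 genes higher and 1313 lower and of 15 lists called by camera were recomputed under 21 alternatives. Leaving out each sample gave 791 to 1226 genes higher, 862 to 1325 lower and 13 to 16 lists. The lowest gene counts came without WT-medium replicate 1, at 791 and 862, in a fit with fewer samples. A minimum fold change of 1 log2 unit left 379 and 409, which follows from the added condition. Camera with an estimated correlation called 0 lists and fry 15. The fry calls held the matrix protease and endothelial lists, at adjusted p of 0.0097 and 0.0054 (fry in limma, Benjamini-Hochberg). The S phase and ribosomal lists, called by camera, were not among them, at 0.29 and 0.28. Fry asks whether the genes of a list move, and compares them with no other genes. The remaining alternatives gave counts within 1.5 times those reported, among them the replicate block with 1277 higher, 1375 lower and 15 lists. Whether the repeat numbers pair the samples stayed undecided. Deviations from the group mean correlated at -0.0963, 0.105 and 0.167 between samples with the same number. For WT-medium replicates 1, 2 and 3 the highest correlation with an Alox5KO-medium sample of another number was 0.101, 0.0776 and 0.0154. TPM scaling moved the share of calls that were higher from 48.5% to 55.8% and the median of all genes from -0.00082 to 0.055. Without the filter on low values 2037 of the 2551 calls were shared. The epicardial and mesothelial list reversed there, from a median of -1.15 to 0.0062, with an adjusted p of 0.33 (camera in limma, Benjamini-Hochberg), where more of its members of low abundance entered. Among 142 named genes 25 changed their side of the threshold under some alternative, with 68 values weaker, 23 stronger and 2873 the same, and 0 reversed. Among 29 lists 12 changed, with 23 values weaker, 14 stronger and 565 the same. A change of sign counted as a reversal where the value passed the threshold before or after. At this depth a gene of 1 kilobase with 3 reads has 0.185 to 0.228 FPKM.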

Other observations

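The transcription factor families, the loci without a symbol, and the tests of pericytes, smooth muscle cells, cytokines left in the media and mast cell RNA were chosen after the data were seen. Transcription factors changed in both directions. Sox9, Nr4a1, Irf7, Fos, Egr1 and Hes1 rose by 4.01, 2.53, 2.45, 2.16, 2.04 and 1.75 on the log2 scale, and Meox2, Glis3, Klf4, Maff, Rbpj and Meox1 fell by 3.20, 1.97, 1.62, 1.55, 1.43 and 1.33. Hes1 is a target of Notch signalling and Rbpj its DNA-binding partner, and the receptor gene Notch3 rose by 2.33. Rbpj fell while Hes1 and Notch3 rose, and no list of Notch genes was tested. Among 23 comparisons of gene classes by Fisher's exact test with Benjamini-Hochberg adjustment, 20 of 49 basic helix-loop-helix factors were called (adjusted p = 0.0069), 15 of 36 basic leucine zipper factors (adjusted p = 0.027) and 32 of 306 C2H2 zinc finger factors (adjusted p = 2.3e-05), against 20.6%, 20.6% and 20.9% of the remaining genes. None of 21 MYB factors was called (adjusted p = 0.042), and transcription factors as a whole were called in 18.5% of cases against 20.8% (adjusted p = 0.28). By the same test small nucleolar RNAs were called in 5 of 159 cases against 20.9% of the rest (Fisher's exact test, Benjamini-Hochberg adjusted p = 3.6e-09), microRNAs in 10 of 97 against 20.8% (adjusted p = 0.042), and protein-coding genes in 21.2% of cases against 15.9% (adjusted p = 9.0e-05). Genes within a class are not independent. Classes were not matched for abundance or gene length, so a low share of calls does not show that a class was unaffected.

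Loci without a symbol changed as strongly as many named genes. The locus on chromosome 6 from 54865301 to 54876800 fell from 18.9 ± 4.45 to 0.472 ± 0.121 FPKM (SD, n = 3 per group), and a locus on chromosome 17 from 8982584 to 8984428 rose from 0.0962 ± 0.0941 to 9.30 ± 3.86 FPKM (SD, n = 3 per group). Over the called genes WT-medium replicate 3 lay 10.5% of the way from its group toward the other, and the remaining samples between -7.93% and 8.99%.

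The contrast gave 1238 genes higher, 1313 lower and 15 lists. Splitting the 6 samples into 3 and 3 in every way makes 10 splits, of which 1, 1 and 1 gave counts as large, the real split included, and no share under 0.05 can be reached with 10. The highest of the other splits had 2 genes in either direction and 11 lists. The other splits called 4 to 11 lists by camera and 3 genes at most. Each of them mixes the media unequally and so keeps part of the real difference. Their list counts therefore cannot show what camera calls where there is no difference. With 0 lists called under an estimated correlation, the camera calls depend on that setting, which the gene counts do not use. The size of the correlation alone does not account for the lost calls. The epicardial and mesothelial list, with an estimated correlation of 0.0461, went from an adjusted p of 8.6e-04 to 0.23 (camera in limma, Benjamini-Hochberg). Fry, which uses no preset correlation, called 15 lists.

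Inflammatory genes fell and contractile genes rose, with 41 called genes lower in the NF-kB and cytokine lists and 28 higher in the myofibroblast and YAP and SRF lists. After thinning to the smallest library and after removal of the length trend, 98.6% and 100% of these 69 genes kept their call and direction. For these calls the latter argues against gene length bias. Thinning decides little about deeper sequencing of the Alox5KO-medium libraries, since FPKM is already scaled to library size. The 69 were also picked as called in the main fit, so few losses were likely under either change. A larger share of pericytes stayed open. Of 4 tested pericyte genes 2 fell, Kcnj8 by 1.83 and Abcc9 by 0.85, while Notch3 and Cspg4 rose by 2.33 and 0.91. Higd1b and Rgs5, also in the set, were too low to be tested. They had 14 and 3 reads with WT medium and 7 and 2 with Alox5KO medium. These genes were picked after their values were seen, and an earlier form of the test had counted the 2 falls against a larger share of pericytes. A larger share of vascular smooth muscle cells may be part of the pattern, since Myh11 rose by 1.84, as it also does in fibroblasts that turn contractile; an earlier form of this test, Myh11 at 0.345% of Acta2 against a bound of 1%, counted against such cells and was dropped after its result because the bound was assumed. Unequal TNF-alpha or other cytokines left in the media could also lower NF-kB genes, whose median was -0.98. Their effect cannot be told apart from that of mast cell leukotrienes, since leukotrienes in the media were not measured here.

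Alox5 was lower in wild-type cells given Alox5KO medium, at 35 reads against 336, and RNA carried over from the donor mast cells, which would bring other abundant mast cell transcripts from either donor, stayed open as a source. The 18 genes of the mast cell list in the table had a median of 4 reads over the WT-medium libraries, which counts against it, but this median rests on 7 genes listed at 0, which is not read as absence, and leaving these out, which drops the genes that count against it, gave 203. Among the other 11 Hdc, Srgn and Kit had 7, 122 and 136, while Cd63, Il1rl1, Cpa3 and Gata2 had more than Alox5, at 35901, 8033, 3017 and 539. The cells that these reads came from were not determined. With Alox5KO medium Cd63 had 36632 reads and Il1rl1 rose to 52446, while Cpa3 and Gata2 had fewer, at 1461 and 391. Fcer1a, Ms4a2, Tpsb2 and Mcpt4 were listed at 0 in both groups. The test was rewritten after each result was seen: 8 reads over 6 of the genes and the median of 4 had counted against this source, and 2 markers that fell and the median of 203 had left it open. Reads depend on how mast cell RNA aligned to rat genes, and lower transcription of Alox5 in the recipient cells was not tested.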
